A study of Bos taurus with 20 samples.

How the data were processed

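Endometrial biopsies of 10 cows, each sampled in an early and a late period after calving, were measured on 20 Agilent 4x44K bovine arrays, 1 per sample. Per the labels' protocols, total RNA was extracted with a column kit, spiked with a one-colour control mix and labelled with Cy3. Per the file headers, the images were read with Agilent Feature Extraction 10.5.1.1, and the deposited intensity values hold, for each spot, the processed signal (background-subtracted and detrended within the array), the mean signal and the local background. The deposited value table of the series holds log2 values. Set against the scanner files, each of its columns matched the log2 processed signal minus the array's 75th percentile, centred per probe on the median of the 20 arrays, with a correlation of at least 0.99996 and a median absolute difference of at most 0.00267. Its scale, centring and direction were therefore known, and it was used as an alternative. The column medians of that table lie in the results of the comparison and the largest row median was 5e-07. All columns of per-sample values were used.

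Values were log2 of the processed signal minus each array's 75th percentile. Control spots and outlier-flagged spots were left out, and spots of a probe were averaged, which gave 43653 probes. Probes were named by accession (22202), symbol (9849), synonym (372) or gene number (1171) through a RefSeq table of the ARS-UCD2.0 assembly, used for names only, and 10059 kept the name of the array's design. A probe entered if it was well above background on at least 8 of the 20 arrays, which 33759 did, and the probe of highest mean represented each gene, which left 19420 genes. Of the named genes, other probes disagreed in sign for SPINT1 (1 probe) and DES (2 probes). In 206 genes at least 1 array value was missing; the list tests took the fitted value there. The depth of an array measurement is its signal over background, given in the report, and the number of arrays limits the precision.

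Late was compared with early in limma 3.58.1 (R 4.3.3; lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) with cow as a fixed block. The pairing comes from the design text and from the titles and animal numbers of the labels. The source names of the late samples carry other cow numbers than the titles, a conflict that the labels do not resolve. Probes of 2 widely separated states argue for the pairing by title. At gaps of 2.5, 3 and 4 log2 units the own cow's other array was the best match for 17, 16 and 19 of 20 arrays. A different cow matched better for 3, 2 and 0 arrays. These were the late arrays of cows 4 and 10 at gaps of 2.5 and 3, and the early array of cow 6 at 2.5. Cow 4 stays undecided, and for cows 6 and 10 the best match depended on the gap. The pairing was also checked over all genes. The deviations of a cow's arrays from the period means correlated between -0.11 and 0.76 (median 0.42), against a median of -0.03 between different cows. In 8 of 10 cows the correlation was above 0.1. By this measure the own cow's other array was the best match for only 7 of the 10 early and 6 of the 10 late arrays. Gene lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry, for lists with at least 5 genes measured. Day trends were fitted per period as a slope per 10 days. The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names the 12 largest rises and the 12 largest falls among genes past the threshold and moving the same way in at least 8 of 10 cows, with symbols only; in each list up to 4 members past the threshold by smallest p, or the 2 of smallest p; and for day trends the 3 genes of smallest p per direction.

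Alternatives were no pairing, pairing as a random effect, normexp background correction (offset 50), quantile normalization, scaling to the median of detected probes, the deposited table, no filter, a filter on all 20 arrays, the mean of a gene's probes, each probe alone, a trended and robust variance, slide as a block, a 1.5-fold minimum and leaving out each cow. Chosen after seeing the data were slide as a random block, slide 3 alone with and without the early sample of cow 9, leaving out cows 4 and 9, exact sign-flip tests of lists and leaving out genes of widely separated states. Scan date could not be run as a block because all arrays shared 1 scan day.

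The late against early test was tested on simulated data with the cow effects and residual spreads of 19214 genes. Of 50 genes changed by 0.5 on the log2 scale 28% were recovered, of 50 changed by 1 82%, of 50 changed by 2 92% and of 50 changed by 3 100%, with 3 false calls. A list shifted by -0.5 was called and no other list was, but the simulated genes were drawn independently of each other. In the real data the estimated correlation was, for example, 0.67 in the macrophage list. The simulation therefore cannot show how often lists of correlated genes are called falsely. The early day trend was simulated on 19214 genes. Of 100 genes with a slope of 0.5 per 10 days 72% were recovered, and of 100 with a slope of 1 92%, with 6 false calls. That simulation used only the spread within cows. The real day trend compares different cows and also carries the spread between them, so these shares are likely too high. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.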

Results

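Endometrial RNA of 10 cows was measured in 2 samples per animal on 1-colour oligonucleotide arrays. Each cow gave a biopsy early after calving, between day 42 and day 86 (mean 60.1 ± 13.4 days, SD, n = 10), and another late, between day 343 and day 436 (mean 388.9 ± 27.5 days, SD, n = 10). Both biopsies came from the uterine horn on the side of the corpus luteum, 7 days after oestrus by the design text. The comparison is therefore between intervals after calving at a cycle day that was matched by design. For an early sample described below, which stayed in the main fits, another cycle stage was left undecided. Each cow's late biopsy followed its early one, so age and sampling order changed with period and were not separated from it. Cows are named here by number, 1 to 10, the same in both periods. Between 71.8% and 80.2% of the 43803 noncontrol spots were well above background on each array, and no probe was saturated. Signal levels are log2 values relative to each array's 75th percentile, and 19420 genes entered the tests, 13308 of them with a gene symbol. The number of arrays limits the precision.

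The first comparison asks which genes differ between the late and the early period within a cow. GPNMB, a transmembrane glycoprotein of phagocytes and pigment cells, fell 7.67-fold (95% interval 4.88 to 12.04, n = 10 cows), from 2.89 ± 0.71 to -0.05 ± 0.64 (SD). CD68, a lysosomal glycoprotein of macrophages, fell 3.47-fold (95% interval 2.49 to 4.82), and VSIG4, a complement receptor of tissue macrophages, fell 2.77-fold (95% interval 2.16 to 3.55). SPIC, a transcription factor of iron-recycling macrophages, fell 3.70-fold (95% interval 2.59 to 5.27), and ATP6V0D2, a subunit of the vacuolar proton pump, fell 4.29-fold (95% interval 3.06 to 6.01). All 5 were lower in 10 of 10 cows, with limma adjusted p between 0.00412 and 0.00641. The probes lie, on the HGSC Btau_3.1 build named in the file headers, on chromosome 4 from 33228129 to 33228188 for GPNMB, on chromosome 19 from 27817472 to 27817531 for CD68 and on chromosome X from 56720756 to 56720815 for VSIG4.

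Of the other genes among the 12 largest falls, SLC11A1, a metal transporter of the phagosome, had a log2 change of -2.28 ± 0.44 (SE, adjusted p = 0.0382), and its probe was well above background on 9 early and 4 late arrays. SLC11A1 was at 1.39 with slide as a block, opposite in sign, and its call was lost on leaving out any 1 of 8 cows. CD300H, an immunoglobulin-like receptor, had -2.01 ± 0.35 (adjusted p = 0.0324), with 1 late array above background. ADTRP was not well above background on any late array and was at least 2.47-fold higher early (adjusted p = 0.00412), a bound that sets the late arrays at the higher of the probe's own signal and the lowest signal well above background. CPD, a carboxypeptidase, had a log2 change of -1.90, and FCN1, a secreted lectin of monocytes named FCN2 on the array, had -1.67. The serine protease KLK6 had -1.81 and the kinesin KIF5C -1.58, both with adjusted p between 0.0441 and 0.0462. The KIF5C call was lost whichever cow was left out and the KLK6 call for 9 of 10 cows.

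Rises were smaller and mostly concerned dim probes. COCH, an extracellular matrix protein, rose by 2.19 ± 0.38 on the log2 scale (SE, adjusted p = 0.0324), from -3.80 ± 1.42 to -1.61 ± 1.16 (SD), in 9 of 10 cows. Its probe lies on chromosome 21 from 42456510 to 42456569. TYRP1, a melanosomal enzyme, rose by 1.66 (adjusted p = 0.0324) and BAI3, an adhesion receptor, by 1.59 (adjusted p = 0.00707), each in 10 of 10 cows. PCK1, the cytosolic enzyme that commits carbon to gluconeogenesis, rose by 1.27 (adjusted p = 0.0462) in 9 of 10 cows. The scaffold protein GRIP1 rose by 1.54, the glucuronyltransferase B3GAT2 by 1.44, the protocadherin PCDH10 by 1.40 and the endoplasmic reticulum protein ERP27 by 1.33. The remaining 4 of the 12 largest rises were the odorant receptors OR2AD1 with 1.48 and OR5V2 with 1.12, the forkhead gene FOXR1 with 1.15 and CDCP2 with 1.14. FOXR1 was well above background on 1 early and 7 late arrays, and BAI3 on 4 early and 10 late arrays.

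In all, 256 genes passed an adjusted p of 0.05 in the fit paired by cow, 151 of them lower late and the rest higher, and 4383 had an unadjusted p under 0.05. The median change of all genes was 0.02. Of the 256, 82 changed at least 2-fold, 22 upward and 60 downward. The share of calls that were higher depended on the scaling, with 41.0% as given, 53.3% after normexp background correction, 51.7% after quantile normalization and 50.6% after scaling to the median of detected probes. Without the pairing 119 genes passed. Leaving out a single cow left between 35 and 159 genes, and 27 genes, 6 higher and 21 lower, passed whichever cow was left out. These 27 included GPNMB, VSIG4, ATP6V0D2, ADTRP, CD68, SPIC, CPD and BAI3, but not COCH, TYRP1 or PCK1. Among the named rises the calls held in 6 of the 10 fits without 1 cow for TYRP1 and CDCP2, 5 for ERP27, 4 for COCH and OR2AD1, 3 for B3GAT2, 2 for GRIP1, PCDH10 and FOXR1, 1 for OR5V2 and 0 for PCK1. Among the falls they held in 5 for CD300H and 4 for FCN1. Of the list members named below as past the threshold, FCGR3A held in 10, MSR1, CCR1 and C5AR1 in 9, NKG7 and TYROBP in 6, CFD in 2, HAND2, NID1, VEGFC, ICAM1, TLR7 and CXCL8 in 1 and CD1E in 0.

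Slide and period largely coincided. Of the 5 slides, 2 held early arrays only, 2 held late arrays only, and slide 3 held the early arrays of cows 9 and 10 with the late arrays of cows 1 and 2. No gene passed with limma when slide was a further block, 366 had an unadjusted p under 0.05, and the standard error of a median gene was 4.81 times as large. Within slide 3 alone, where the early and late arrays were of different cows and could not be paired, no gene passed and 1722 had an unadjusted p under 0.05. A random slide block left 35 genes, 7 higher and 28 lower, all of them among the 256. The log2 change of GPNMB was -2.59 with slide as a block and -3.59 within slide 3, and that of CD68 was -1.80 and -2.99. The early sample of cow 9, on slide 3, had the highest early level of both, at 4.63 and 0.57, so the slide 3 values lean on it. COCH was at -0.16 with slide as a block, opposite in sign, and at 3.35 within slide 3. Of the other named rises, TYRP1 was at -1.47 within slide 3, PCK1 at -0.46, CDCP2 at -0.27 and OR5V2 at -0.84, all opposite in sign, and GRIP1 was at -0.21 with slide as a block. Of the 256 genes, 221 had the same sign with slide as a block.

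**Figure D1:**
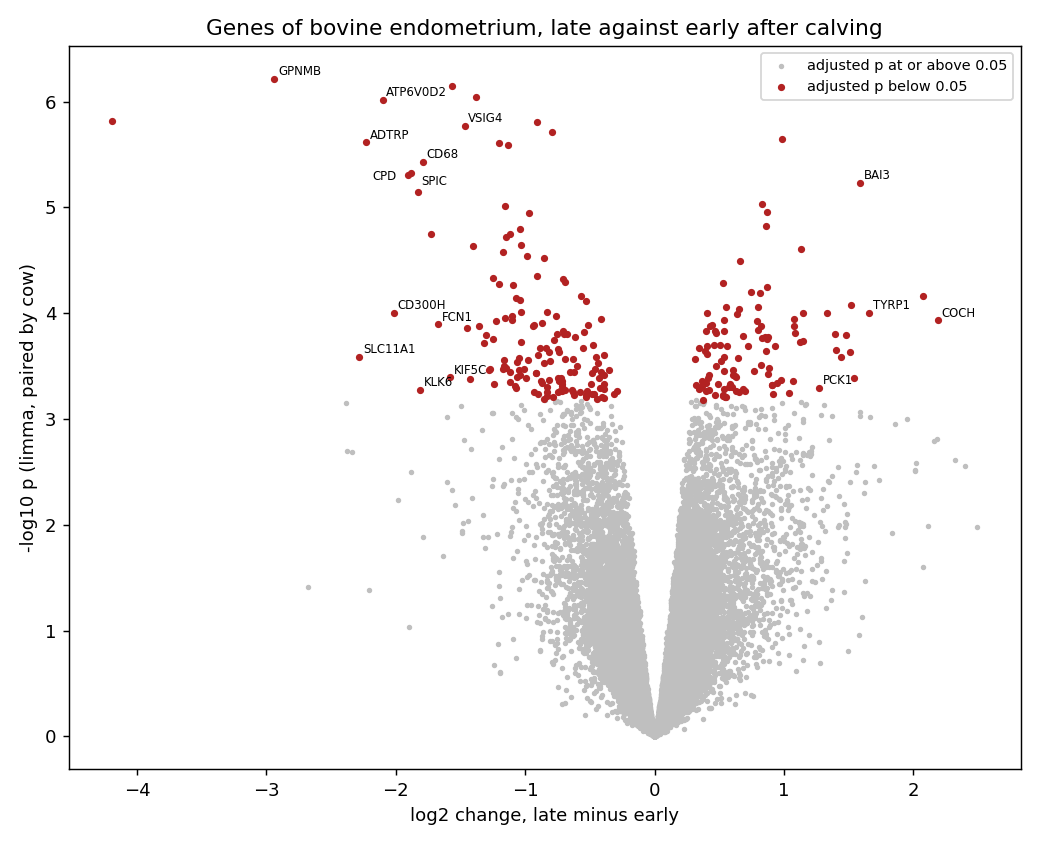
Each point is 1 of 19420 genes, with its log2 change (late minus early) on the horizontal axis and -log10 of the limma p, paired by cow, on the vertical axis; red points are the 256 genes with an adjusted p below 0.05, and the 12 largest falls and 4 of the rises with a symbol are labelled. The largest labelled fall is GPNMB at -2.94 and the largest labelled rise is COCH at 2.19.

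**Figure D2:**
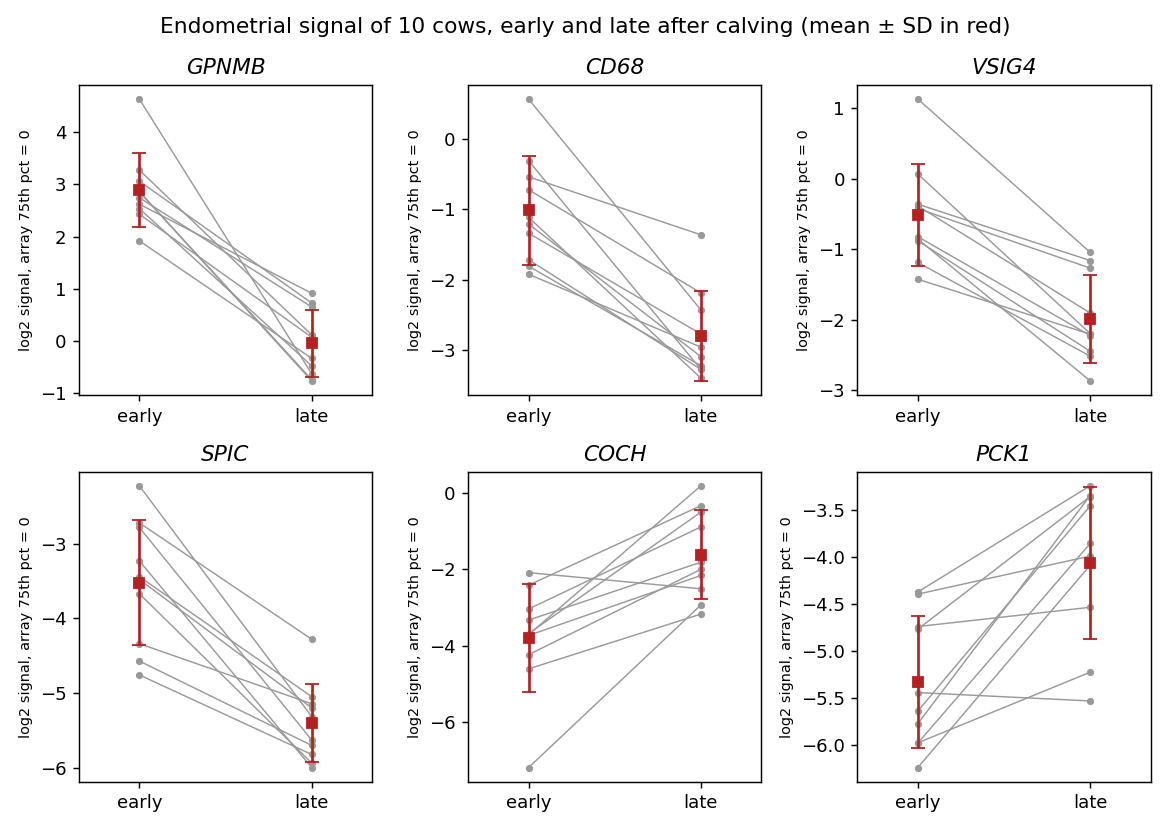
Log2 signal relative to the array's 75th percentile in the early and late sample of each of 10 cows (grey lines) with mean ± SD (red) for 6 genes. GPNMB, CD68, VSIG4 and SPIC were lower late in 10 of 10 cows, and COCH and PCK1 were higher late in 9 of 10.

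The second comparison sets the same periods against gene lists fixed before the data were examined. Camera with a preset inter-gene correlation of 0.01 called 18 of the 31 lists tested. None was called with an estimated correlation, where the smallest adjusted p was 0.431, and fry called 1, the macrophages and monocytes. An exact sign-flip test of each list's mean change per cow, added after seeing the data, called 6: macrophages and monocytes, T and NK cells, red blood cells, matrix remodelling, the steroid receptor and prostaglandin list, and antigen presentation, each with an adjusted p of 0.0404. Adjusted p-values for lists below are from camera unless another test is named.

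The macrophage and monocyte list fell by 0.78 ± 0.57 on the log2 scale (mean ± SD of 10 cows), lower in 10 of 10 cows (adjusted p = 1.33e-11, and adjusted p = 0.431 with an estimated correlation). Of its 15 members tested, 4 were lower over all genes and 14 adjusted over the list alone. The 4 were VSIG4, CD68, the scavenger receptor MSR1 with a log2 change of -0.85, and the signalling adaptor TYROBP with -1.07. CD163, the haemoglobin scavenger receptor, was at 0.12 ± 0.41 (SE, adjusted p = 0.883). The list's mean change was -0.94 with slide as a block (95% interval over cows -3.85 to 1.96; camera adjusted p = 0.000237). It was -0.79 with slide as a random block (adjusted p = 9.69e-12). Within slide 3 it was -1.51 (camera adjusted p = 4.75e-09), and -0.91 without the early sample of cow 9. The slide 3 comparison was unpaired, between different cows, and its p does not measure the spread over cows.

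Other immune lists also shifted downward. T and NK cell markers had a mean of -0.28 ± 0.31 (SD, n = 10 cows; adjusted p = 0.00308, and 0.452 as the adjusted p with an estimated correlation), with NKG7, a cytotoxic granule protein, the 1 member of 18 past the threshold over all genes at -1.20 and 5 lower adjusted over the list alone. Complement genes had a mean of -0.23 (adjusted p = 0.000252, and adjusted p = 0.431 with an estimated correlation). Of 27 members, 2 were lower over all genes, the anaphylatoxin receptor C5AR1 at -1.17 and factor D, CFD, at -0.62, while 12 were lower and 2 higher adjusted over the list alone. The C5AR1 probe was well above background on 9 early and 3 late arrays. The complement mean was -0.14 without cow 4 and -0.10 without cows 4 and 9. Antigen presentation genes had a mean of -0.30 (adjusted p = 5.95e-05, and adjusted p = 0.431 with an estimated correlation), with CD1E at -1.07 the 1 member of 22 past the threshold and 8 lower adjusted over the list alone. Chemokines and their receptors had a mean of -0.22 (adjusted p = 0.0105, and adjusted p = 0.465 with an estimated correlation), with CCR1 at -1.40 and the neutrophil attractant CXCL8 at -1.15, 2 of 37 over all genes and 3 adjusted over the list alone. The chemokine call was lost without cow 4, without cows 4 and 9 and with the filter on all 20 arrays (adjusted p = 0.0923, 0.124 and 0.0651). The chemokine means there were -0.11, -0.06 and -0.13. The antigen presentation call was lost within slide 3 (adjusted p = 0.162). The complement, antigen presentation and chemokine calls were lost with slide as a block (adjusted p between 0.133 and 0.360), with means of -0.15, -0.33 and -0.06. For antigen presentation the mean did not shrink and its 95% interval widened, from -0.47 to -0.13 without slide and from -1.40 to 0.74 with it.

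Interferon-stimulated genes had a mean of -0.36 ± 0.68 (SD, n = 10 cows; adjusted p = 5.06e-06, and adjusted p = 0.465 with an estimated correlation). None of 37 members passed over all genes and 3 were lower adjusted over the list alone. LGALS3BP had -0.31 (adjusted p = 0.0623) and EIF2AK2, the double-stranded RNA-activated kinase, -0.70 (adjusted p = 0.0778). Cow 1 had a change of -2.18, and without it the mean was -0.16 (adjusted p = 0.00242). The mean was -1.31 with slide as a block (camera adjusted p = 1.41e-09), with a 95% interval over cows of -4.28 to 1.66. That fit gives cow 1 more weight than the plain mean does, so it does not show a larger fall apart from that cow. Lists that camera did not call included inflammation and Toll-like receptor signalling (adjusted p = 0.158), in which ICAM1 at -0.91 and TLR7 at -1.12 passed over all genes and 2 of 38 adjusted over the list alone. The TLR7 probe was well above background on 8 early and 3 late arrays. The inflammation list was called without the filter and with the mean of a gene's probes (adjusted p = 0.0361 and 0.0153). It was also called with each probe on its own and within slide 3 (adjusted p = 0.0144 and 0.00682). Neutrophil markers were also not called (adjusted p = 0.0715); FCGR3A, an Fc receptor that macrophages and NK cells share, passed at -0.97, 1 of 11 on either adjustment. The neutrophil list was called with the filter on all 20 arrays, with each probe on its own, without cow 2 and without cow 3 (adjusted p = 0.0112, 0.0125, 0.0311 and 0.0427), and the B cell list without cow 2, 3 or 7 (adjusted p = 0.0484, 0.0292 and 0.0171). B cells (adjusted p = 0.0837, with CXCR5 at -0.71 and BLK at -0.50) and plasma cells (adjusted p = 0.716, with PIM2 at 0.26 and PRDM1 at -0.30) had no member past the threshold on either adjustment. Mast cells (adjusted p = 0.333) had TPSB2 at -0.60 and FCER1A at -0.91, with 3 of 8 lower adjusted over the list alone. Mucosal and antimicrobial defence genes (adjusted p = 0.708) had DEFB5 at -2.37 and DEFB4A at -2.34, 2 probes that carry 1 accession and may measure 1 transcript, neither past the threshold (adjusted p = 0.0712 each), with 3 lower and 2 higher of 28 adjusted over the list alone.

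Matrix and stromal lists had negative means, which turned sign with slide as a fixed block. The slide-blocked mean gives single cows more weight than the plain mean and turns the sign of the change of cow 4. That change was -1.47 for collagens, -1.64 for matrix remodelling and -0.76 for fibroblasts, so cow 4 adds to the reversal. Within slide 3 the means of these lists were negative, but there the early sample of cow 9 carried much of their size. Values without that sample, chosen after seeing the data, are given beside them. Collagens and matrix structure had a mean of -0.42 ± 0.55 (SD, n = 10 cows; adjusted p = 5.38e-10, and adjusted p = 0.452 with an estimated correlation). Of 33 members 32 had negative values, the basement membrane gene NID1 passed over all genes at -0.50, and 8 were lower adjusted over the list alone. The mean was 0.65 with slide as a block, called in the opposite direction (camera adjusted p = 0.000105). Fitted on the list's mean per array, the change there was 0.62, with a 95% interval over cows of -0.97 to 2.22. The collagen list had other values as follows. Its mean was -0.42 with slide as a random block (adjusted p = 5.64e-10) and -0.66 within slide 3 (-0.38 without the early sample of cow 9). Matrix remodelling had a mean of -0.35 (adjusted p = 1.8e-05, and adjusted p = 0.431 with an estimated correlation), with MMP2 at -0.58 and PLAU at -0.85, none past the threshold over all genes, and 4 lower and 1 higher of 25 adjusted over the list alone. That mean was 0.88 with slide as a block (adjusted p = 0.00116; 95% interval over cows -0.87 to 2.64) and -0.34 within slide 3 (-0.15 without the early sample of cow 9). Cow 4 had a change of -1.64, and without it the matrix remodelling mean was -0.21. The collagen mean was -0.30 without cow 4 and -0.20 without cows 4 and 9. Stromal fibroblast markers had a mean of -0.31 (adjusted p = 0.0046, and adjusted p = 0.452 with an estimated correlation), with HAND2, a progesterone-responsive transcription factor, at -0.87 the 1 of 12 past the threshold and 3 lower adjusted over the list alone. The fibroblast mean was 0.14 with slide as a block (95% interval over cows -1.83 to 2.11) and -0.64 within slide 3, where it was 0.01 without the early sample of cow 9. Over all slides it was -0.19 without cow 9, and the fibroblast call was lost without cows 4 and 9 (mean -0.12, adjusted p = 0.0728). Smooth muscle (adjusted p = 0.477, with CALD1 at -0.31 and DES at 0.34) and endothelium (adjusted p = 0.489, with ENG at -0.31 and CDH5 at -0.29) were not called, with no member past the threshold on either adjustment. Smooth muscle was called downward within slide 3 (mean -0.63, adjusted p = 0.011), with a mean of -0.16 without the early sample of cow 9.

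Growth factor, Wnt and hormone lists had smaller negative means. The IGF and peptide growth factor list had -0.30 (adjusted p = 0.000166, and adjusted p = 0.431 with an estimated correlation), with IGF2R at -0.40 and IGFBP4 at -0.55, none of 33 past the threshold over all genes and 6 lower adjusted over the list alone. The Wnt list had -0.25 (adjusted p = 0.00414, and adjusted p = 0.452 with an estimated correlation), with the secreted antagonists SFRP1 at -0.85 and SFRP4 at -1.89, none of 29 over all genes and 3 adjusted over the list alone. Steroid receptor, prostaglandin and oxytocin genes had -0.20 (adjusted p = 0.022, and adjusted p = 0.431 with an estimated correlation), with TBXAS1 at -0.83 and HSD11B2 at -0.62, none of 29 over all genes and 1 adjusted over the list alone. That call was lost without cow 4, without cow 6, with each probe on its own and within slide 3 (adjusted p = 0.0674, 0.0561, 0.192 and 0.598). Immediate early and heat shock genes had -0.25 (adjusted p = 0.00633, and adjusted p = 0.465 with an estimated correlation), with HSPA6 at -0.60 and NR4A1 at -0.39 and none of 31 past the threshold on either adjustment, a call lost without cow 4 (adjusted p = 0.0883) and without cows 4 and 9 (adjusted p = 0.0899). Without cow 4 the steroid receptor mean was -0.12 and the immediate early mean -0.14. Without cow 9 the Wnt mean was -0.17, and without cows 4 and 9 the growth factor mean was -0.17. The growth factor mean with slide as a block was 0.27, the steroid receptor mean 0.41 and the immediate early mean 0.05, all opposite in sign. The Wnt call was lost there (adjusted p = 0.32) at a mean of -0.22, with a 95% interval of -1.64 to 1.19, against -0.50 to -0.01 without slide. Angiogenesis genes were not called (adjusted p = 0.118), with VEGFC at -0.45 past the threshold, 1 of 29 on either adjustment. They were called without the filter, with the mean of probes, with each probe on its own, within slide 3 and without cow 5 (adjusted p between 0.00316 and 0.0393).

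Epithelial lists had positive means. Epithelial markers had 0.31 ± 0.41 (SD, n = 10 cows; adjusted p = 0.00414, and adjusted p = 0.465 with an estimated correlation), with SPINT1 at 0.44 and KRT18 at 0.42 and none of 19 past the threshold on either adjustment. Ciliated epithelium had 0.50 ± 0.84 (adjusted p = 0.00414, and adjusted p = 0.465 with an estimated correlation), with CCDC39 at 1.004 and CFAP53 at 0.33, none of 13 over all genes and 1 adjusted over the list alone. Both calls were lost without cows 4 and 9 (means 0.18 and 0.17, adjusted p = 0.0625 and 0.181), an alternative added after seeing the data. Without cow 9 alone the means were 0.20 and 0.35. Red blood cell genes had 0.45 (adjusted p = 0.0266, and adjusted p = 0.431 with an estimated correlation), with EPB42 at 1.17 and AHSP at 0.29, none of 5 over all genes and 3 adjusted over the list alone, a call lost without cow 2, without cow 4, without the filter and within slide 3 (adjusted p = 0.0576, 0.0515, 0.184 and 0.212). The ciliated mean with slide as a block was -0.22 and the red blood cell mean 0.03.

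Mitochondrial respiratory chain genes had a mean of 0.11 (adjusted p = 0.002, and adjusted p = 0.57 with an estimated correlation), with NDUFB3 at 0.27 and NDUFA1 at 0.25 and none of 38 past the threshold on either adjustment, a call lost without cow 9 (adjusted p = 0.0675). Cytosolic ribosome genes had 0.07 (adjusted p = 0.0208, and adjusted p = 0.796 with an estimated correlation), with RPL34 at 0.82 and RPL22 at 0.41, none of 53 over all genes and 1 adjusted over the list alone, a call lost without cow 1, 6 or 10 (adjusted p = 0.09, 0.0918 and 0.252), under quantile normalization (adjusted p = 0.138) and without the filter (adjusted p = 0.0615). Not called were proliferation (adjusted p = 0.489, with TTK at 0.60 and RACGAP1 at -0.45), endoplasmic reticulum protein folding (adjusted p = 0.859, with SEL1L at -0.48 and PDIA3 at 0.31) and cholesterol and fatty acid synthesis (adjusted p = 0.3, with ACACA at -0.77 and ELOVL6 at 0.43). Proliferation was called upward without cow 4 (mean 0.25, adjusted p = 0.0159) and without cows 4 and 9 (mean 0.34, adjusted p = 0.00147). These camera p-values rest on the preset correlation of 0.01, where 0.58 was estimated for the list over all cows, and do not measure the spread over cows. Without cow 4 the list's change ran from -0.51 in cow 9 to 1.14 in cow 10. Cholesterol synthesis was called downward without cow 9 (mean -0.17, adjusted p = 0.00249) and without cows 4 and 9 (mean -0.12, adjusted p = 0.0148). Protein folding was called upward with slide as a block (mean 0.49, adjusted p = 2.74e-05) and within slide 3 (mean 0.13, adjusted p = 0.0483). With slide as a block the protein folding change had a 95% interval over cows of -0.38 to 1.36, which spans both signs. The camera p-values of protein folding rest on the preset correlation of 0.01, where 0.36 was estimated over all cows. They do not measure the spread over cows. Luteal phase secretory products (adjusted p = 0.709) had a mean of 0.03 and a median of -0.13, of opposite sign, with HSD17B11 at 0.34 and CTSL at 0.69. Of these lists, protein folding and cholesterol synthesis each had 1 member lower adjusted over the list alone and the others none. The trophoblast list had 3 members measured and was not tested as a list; PAG8 had 0.27 (adjusted p = 0.0763) and PAG17 0.59 (adjusted p = 0.231).

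**Figure D3:**
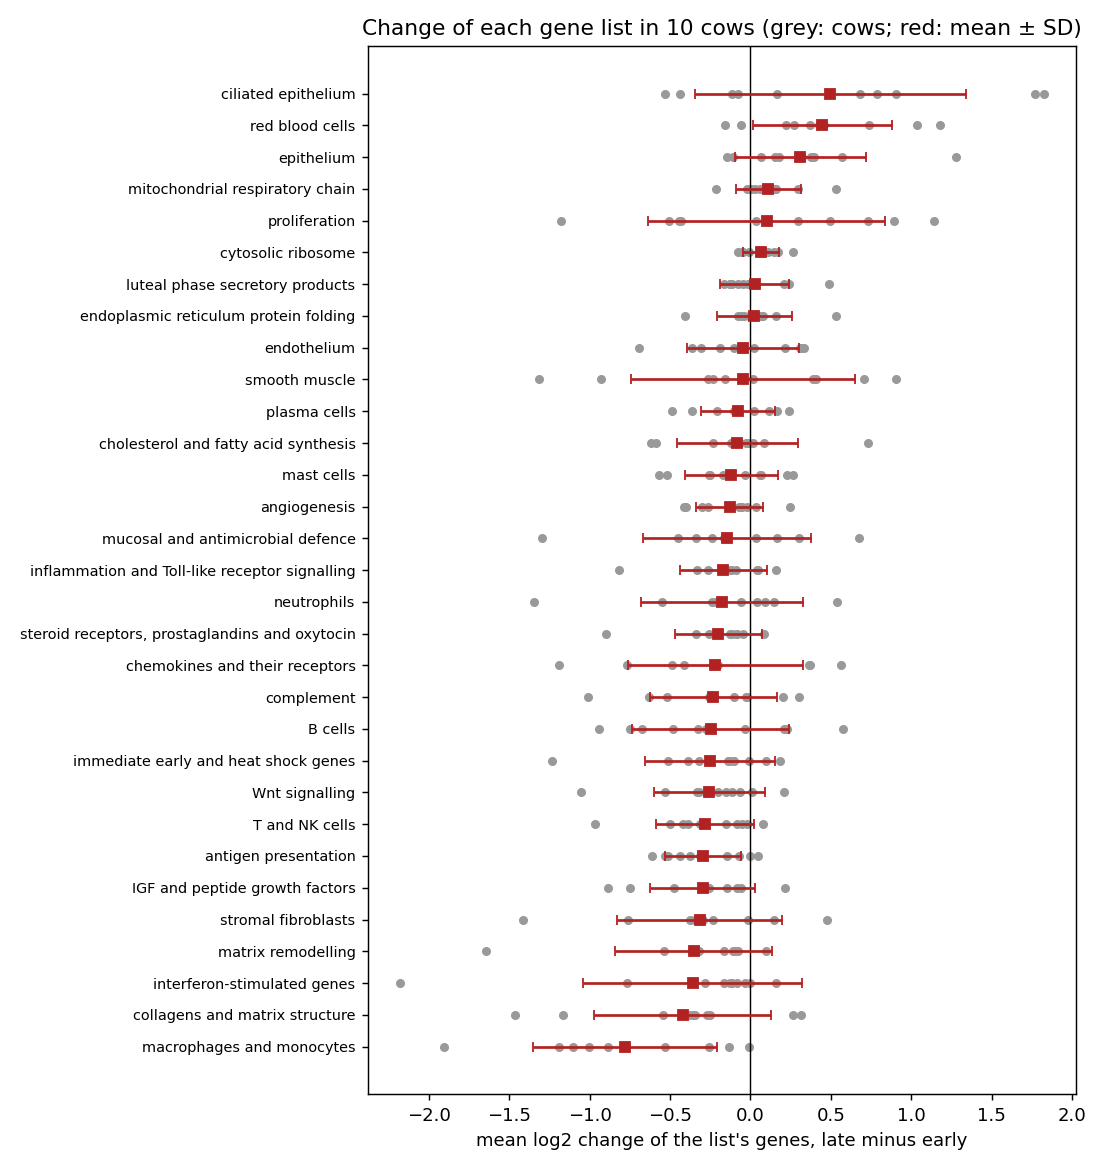
Mean log2 change (late minus early) of the genes of each of 31 lists in each of 10 cows (grey points), with mean ± SD over the cows (red). The macrophage and monocyte list lies lowest at a mean of -0.78, with 10 of 10 cows below 0, and the ciliated epithelium list lies highest at 0.50, with cows on both sides of 0.

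The third comparison asks whether expression followed the day after calving within a period, over 10 cows each. Within the early period no gene passed with limma, and 1098 of 19420 had an unadjusted p under 0.05. That is close to the share that chance alone would give at this threshold. The smallest adjusted p was 0.287. The rises of smallest p among genes with a symbol were those of VIL1, an actin-bundling protein of microvilli, at 1.16 ± 0.22 log2 units per 10 days (SE, adjusted p = 0.581), DSC3 at 0.83 and SLC38A11 at 0.62. The falls of smallest p were those of TMEM254 at -0.42, SPN, a leukocyte sialoglycoprotein, at -0.33 and EVI2B at -0.40 (adjusted p between 0.581 and 0.831). Within the late period no gene passed with limma either, 267 had an unadjusted p under 0.05 and the smallest adjusted p was 1. The late count is below the share that chance alone would give. In the late period the genes of smallest p were SCN3A, SMCO3 and C15H11orf42, with slopes of 0.19, 0.28 and 0.15, and TAFA5, PCBP3 and TMEM216, with -0.17, -0.13 and -0.29. Without cow 10, 1 transcript passed in the early period, DN521914 (slope 0.74, adjusted p = 0.0406), named after its value was seen.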

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

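The tests in this part that set the macrophage, interferon and cow 4 patterns against explanations were chosen after those results were seen; the test of other splits was written before. A value was singled out where its gap to the nearest of the other 9 samples of its period was a large share of the range, by a critical ratio for 10 values. Of 238 groups tested 44 were, where chance would give about 11.9. The early sample of cow 9 held 12 of them, the late sample of cow 3 held 10 and the early sample of cow 4 held 7.

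Whether 256 genes could come from chance was tested by turning the sign of some cows. Of 100 assignments that part all 10 pairs, drawn from 512, 1 gave as many genes, the real one, and the highest of the others gave 0. The others mix early and late samples within each group, unlike the real one, so chance is a poor account of the count.

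The macrophage and monocyte markers were lower late. Less stroma in the late biopsies would lower stromal markers as much. The macrophage change lay -0.645 ± 0.58 (SD, n = 10) below the mean of the fibroblast, endothelial and smooth muscle lists, in 9 of 10 cows (exact sign-flip test, two-sided p = 0.00781). That argues against an even loss of these stromal cells as the whole cause. However, endothelium and smooth muscle hardly moved (means of -0.05 each), while fibroblasts were at -0.31. The macrophage change lay above that of fibroblasts in cows 3, 8 and 9 and below it in the others. A loss of fibroblasts alone was not tested and stays open. Within slide 3 smooth muscle was also called downward (-0.63, and -0.16 without the early sample of cow 9). Slide stays open, since it largely coincides with period: with slide as a block the mean change was -0.942, with a 95% interval over cows of -3.85 to 1.96 that holds both 0 and the value without slide. The camera call was kept there (adjusted p = 0.000237), but the same fit also called collagens upward at 0.65 (adjusted p = 0.000105), against their fall without slide. As a hypothesis, macrophages may have been fewer or in another state late after calving; these arrays do not separate number from state.

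The early sample of cow 1 had interferon-stimulated genes at 1.90, against -0.17 ± 0.25 (SD) in the other 9 early samples. Without cow 1 the list's mean change was -0.157 (exact sign-flip test, two-sided, n = 9, p = 0.0586), against -0.36 with it, so a single early sample may account for much of the size of the list's fall. By the criterion written for this test, these values count for a single early sample as the cause. Camera at the preset correlation still called the list without cow 1 (adjusted p = 0.00242). With an estimated correlation camera did not call it even over all cows (adjusted p = 0.465). Of the 9 other cows 8 were lower, but cow 8 was at only -3.16e-05 and cow 10 at -0.77. Whether cow 1 is the whole cause stays open. What raised these genes in that sample was not tested. EIF2AK2 was at 1.22 in the same sample.

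The early sample of cow 4 stood apart, with a median correlation of 0.936 with the other arrays, where the others had 0.961 to 0.985, and ESR1, PGR and OXTR, chosen after their values were seen, were highest of the 20 arrays there, OXTR at 4.29 against -2.09 ± 1.66 (SD) in the other early samples, and PENK was at -2.08 against 5.54 ± 0.66. Another stage of the oestrous cycle is a candidate explanation, but the share of the luteal list that was to lie below the other early samples, 70% as written down for the test, was 42.9%, which by the written criterion would have counted against it. For poor hybridisation 1 of 6 array measures lay outside the range of the other 19, which by the written criterion would have counted for it, but these were the outlier spots, at 3 the fewest, which points the other way. Both verdicts were changed to undecided after the values were seen. Over probes with 2 widely separated states, the early array matched its own cow best at each of 3 gaps (77.3%, 85.7% and 93.3%, against 73.9%, 77.6% and 86.7% for the best other), while the late array did so at none (best match in 3 of 6 combinations), which leaves RNA from another animal undecided.

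In the early sample of cow 4 the matrix remodelling list was at 1.47, the steroid receptor, prostaglandin and oxytocin list at -0.213, immediate early and heat shock genes at 1.66 and protein folding at 3.08, all high, while COCH was low at -7.19, AHSP at -4.42 and HSD11B2 at 0.601. In the early sample of cow 9 epithelial markers were low at -0.284 against 0.999 ± 0.17 (SD) in the others, with SPINT1 at -2.15 and KRT18 at 1.33, while fibroblast markers were high at 1.39 and the Wnt list at -0.594. The same sample was high for GPNMB at 4.63, ADTRP at -3.35, ATP6V0D2 at -2.18, CPD at 0.282, DES at 3.77, PRDM1 at 4.20 and IGFBP4 at 3.26. In cow 3 the B cell list was high early at -2.43 and late at -2.21, as was CXCR5 at -1.83 and -3.54. Its late sample was also high for BLK at 0.113, NKG7 at 0.541, FCN1 at -1.56, RACGAP1 at -3.91, neutrophil markers at -3.23, inflammation at -1.32, chemokines at -1.63 and proliferation at -0.109.

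Single values apart from the rest were fibroblast markers in the late sample of cow 6 at 0.876, TYRP1 in the late sample of cow 1 at -6.42, CDH5 in the early sample of cow 7 at -3.02, PAG17 in the late sample of cow 7 at -3.59, and HSD17B11 in the early sample of cow 10 at 1.96. In the late sample of cow 9 ICAM1 was at -4.15 and NDUFA1 at 4.97. HSPA6 was at -6.76 in the early sample of cow 5, and SEL1L at -4.87 and ACACA at -4.86 in the early sample of cow 2. The spike-in fit of the early array of cow 6 had an intercept of -1.65 on the log10 scale, against -0.764 ± 0.087 (SD) in the other 9 early arrays.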

How the results depend on the processing

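Slide as a random block, slide 3 alone, leaving out cows 4 and 9, the exact sign-flip test and leaving out genes of separated states were chosen after seeing the data. The cause was not tested for the changes below unless stated. Without the replicate block 119 genes passed (45 higher, 74 lower), 88 of them shared with the 256; with the replicate block as a random effect 733 passed (380 and 353), 217 shared. The pairing changed no list count, at 18 in each of these fits. List tests of the random-effect, trended variance and single-probe settings used cameraPR on the moderated t instead of camera. Higher genes numbered 183 after quantile normalization, 159 with the median of detected probes and 63 with a 1.5-fold minimum, and lower genes 262 with each probe on its own. Without the filter 114 passed (51 and 63) among 25381 genes tested, more tests than the 19420. Leaving out 1 cow gave 35 to 159 genes, 8 to 97 higher and 27 to 114 lower, with 44, 71, 61, 152, 159, 72, 151, 41, 115 and 35 genes without cows 1 to 10 in turn, and 15 to 20 lists. Leaving out cows 4 and 9 gave 202 genes, 127 shared, and 15 lists; leaving out genes of separated states gave 256. With slide as a random block 35 passed (7 and 28); with slide as a block 0 genes (0 higher, 0 lower; 366 at an unadjusted p under 0.05) and 10 lists; within slide 3 alone, with 4 arrays, 0 genes (0 and 0) and 19 lists. Camera with an estimated correlation called 0 lists, fry 1 and the exact sign-flip test 6. The early day trend had 0 to 1 genes on leaving out 1 cow and the late one 0; both had 0 with quantile normalization, no filter and the deposited table, the other alternatives run for day trends. The deposited table gave 255 genes, 254 shared.

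With slide as a block these log2 changes turned sign, none past the threshold: COCH -0.16, GRIP1 -0.21, SLC11A1 1.39, CFAP53 -0.64, ENG 0.62, PIM2 -1.07, PRDM1 0.46, TPSB2 0.18, FCER1A 1.21, AHSP -0.40, PAG17 -1.83, NID1 0.28, MMP2 0.38, PLAU 0.28, ICAM1 0.0701, RACGAP1 0.58, HSPA6 0.95, RPL34 -0.26 and RPL22 -0.38. List means that turned were ciliated epithelium -0.22, fibroblasts 0.14, red blood cells 0.0254 (the test's direction turned, not the mean), collagens 0.65, matrix remodelling 0.88, steroid receptors 0.41, growth factors 0.27, mucosal defence 0.98 and immediate early genes 0.0455; collagens, matrix remodelling and mucosal defence were called upward, as was protein folding (0.49). For each of these upward list calls the interval over cows spanned both signs. Within slide 3 TYRP1 was -1.47, PCK1 -0.46, CDCP2 -0.27, OR5V2 -0.84, DES -0.72, EPB42 -0.70, PAG17 -0.19 and TTK -0.60. DES was -0.0819 with the mean of its probes. The macrophage list was negative under every alternative run, from -1.51 to -0.60. Dim probes limit the genes well above background in few samples of a period, such as FOXR1.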

Other observations

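Outside the rule for named genes, and chosen after their values were seen, several further genes passed whichever cow was left out. LOC782922, which the array describes as similar to prostaglandin F synthetase II, fell 18.3-fold (95% interval 9.03 to 36.9; limma adjusted p = 0.00412) in 10 of 10 cows. The iron exporter SLC40A1 had a log2 change of -0.91, the adenosine receptor ADORA3 -1.14, MS4A7, a membrane protein of monocytes and macrophages, -1.15, the junctional adhesion molecule JAML -1.38 and the neural cell adhesion molecule NCAM1 -1.15. GPX5, a glutathione peroxidase, had 0.99.

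Some probes fell into 2 states far apart, and these states followed the cow. At a gap of over 4 log2 units there were 30 such probes, 27 of which had the same state in both samples of all 10 cows, among them BOLA-DQB1 and BOLA-DQA5, class II histocompatibility genes. Gaps of 2.5, 3 and 4 were tried. The own cow's other array was the best match for 17, 16 and 19 of the 20 arrays, with 0, 2 and 1 ties, so a different cow matched better for 3, 2 and 0 arrays. At gaps of 2.5 and 3 the late array of cow 4 matched another cow better than its own early array, with 77.3% and 85.7% agreement for its own and 85.2% and 87.8% for the other. The late array of cow 10 did so at the same gaps and the early array of cow 6 at 2.5.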
